A study of Mus musculus with 134 samples.

How the data were processed

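RNA from the thymus of 67 C57BL/6 mice, an inbred laboratory strain, was measured on membrane arrays of mouse cDNA clones. Per the labels, each tissue was broken up by bead-beating with 1.0 mm beads, total RNA was taken up on RNeasy columns, and 5 micrograms were reverse transcribed with Superscript II in the presence of radioactive dCTP. The labelled cDNA was hybridised to a mouse cDNA clone set of the 17K kind, which is printed as a pair of arrays, A and B. Each mouse therefore gave 2 arrays, and the 134 arrays are 1 A and 1 B array for each of the 67 mice. Mice fed ad libitum received regular feed throughout. Restriction began after 13 weeks of regular feed and used a fortified feed, given at 90% for 1 week, at 75% for 1 more week and at 60% until the mice were killed.

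The authors deposited 1 value per probe and array, in a unit recorded here as a score: a z-score, whose mean is 0 and whose standard deviation is 1 over the 8448 probes of each array. This was tested on the values themselves. The deposited scores have 2 decimals, run from -8.78 to 3.94, and hold 0 missing values. Image analysis, background correction and whether a logarithm was taken before the scaling are not given in the sources used here. Differences are therefore given in z-score units, that is, in standard deviations over the probes of 1 array, and never as folds. A z-score sets each probe against the other probes of the same array, so a common rise or fall of all transcripts per cell would not be seen. The design fixed beforehand had assumed log2 values. The z-scores were fitted with the same limma models, since they are continuous values and log2 intensities were not used here. The scale gives no signal over background, so the precision of a value rests on the number of arrays.

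The A and B tables were scaled separately and hold different probes, so each was fitted on its own. The p-values of the 16896 probes of both tables were then adjusted together. No probe was left out. Probes were named through the platform annotation, in which 9663 probes have 1 gene symbol, 436 have several and 6797 have none. Of the first kind, 9641 were found by Entrez gene number in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. The named probes stand for 7151 genes, of which 1858 have more than 1 probe. A gene with several probes is represented by the probe with the highest mean over all mice. No coordinates are given because the array annotation names no genome build.

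Groups were taken from age, diet and sex on the labels. Ages fall into 4 bands: juvenile (17 to 44 days), young adult (169 to 194 days), middle-aged (472 to 499 days) and old (673 to 743 days). With diet and sex this gives 14 groups. The labels number the mice from 1 to 67 and each number occurs once, so the numbers pair no mice between groups. The groups recur along these numbers in 5 cycles, and what the number stands for is not stated. For mouse 27 the description repeats that of mouse 1, a juvenile, while its title and its age entry give 714 days. It was used as an old mouse and also left out as an alternative.

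Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with statmod 1.5.0 for array weights. The slope over age used the 40 mice fed ad libitum, with age in days and sex as terms, and is given per 100 days. The comparison within juveniles used those 10 mice with sex as a term. All other comparisons were contrasts of the 14 group means over the 67 mice, which share 1 estimate of the spread. A probe passed at a Benjamini-Hochberg adjusted p under 0.05 over both tables, with no minimum size. Every adjusted p of a gene below is limma's with this adjustment. An error given for a difference is its standard error from limma, and one given for a group is the standard deviation over mice. All tests were two-sided.

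For each comparison the text draws named genes from this rule: the 5 passing genes with the largest increase and the 5 with the largest decrease, up to 4 members of each gene list with the smallest p whether or not they passed, Foxn1, Rag1, Ptcra, Aire, Adipoq, Igf1 and Cdkn2a where measured, and in the comparison of the sexes every measured sex-linked gene. Of the genes always to be named, Igf1 has a probe with 1 symbol, and the others are not analysed here. Where no named gene passed, the genes with the smallest p in each direction are given instead, a choice made after the values were seen. Gene lists were written for 22 groups: thymocytes, proliferation, cortical thymic epithelium, medullary thymic epithelium, adipocytes, B lymphocytes and plasma cells, macrophages with dendritic cells and antigen presentation, extracellular matrix and fibroblasts, endothelium, red blood cells, skeletal and cardiac muscle, parathyroid, interferon response, electron transport chain and ATP synthase, cytosolic ribosomal proteins, heat shock and protein folding, lysosome, glucocorticoid response, oxidative stress and detoxification, cholesterol synthesis, apoptosis regulators, and sex-linked genes. The parathyroid list has 0 measured members, and the other 21 were tested. Several lists are thinly covered: 6 of the 40 thymocyte genes, 8 of the 20 cortical epithelial genes and 3 of the 29 B lineage genes have a probe. A list was tested with limma's camera on all its probes, which asks whether its members moved more in 1 direction than the other probes did. Repeat probes of a gene count as separate members, as in the red blood cell list with 29 probes of 9 genes. The correlation between members was preset at 0.01, and the test was repeated with the correlation estimated from the data. Camera p-values were adjusted over the 21 lists of a comparison. Members of a list were also counted with p-values adjusted over the list alone.

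Groups, models, gene lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were quantile normalisation, median centring, scaling by median and median absolute deviation, leaving out the dimmest 25% of probes, the cycle of running numbers as a block, the running number as a covariate, fits on the compared groups alone, exact age within bands, array weights, a trended robust prior, no moderation of the variance, adjustment per table, 1 probe per gene, leaving out mouse 27, and leaving out each mouse in turn. Slopes on log2 of age and over adults alone, and contrasts with juveniles of 1 age, were fixed as well. After the data had been seen, fits without mice 1 to 12, with these mice as a block, with the first principal component as a covariate and without the 3 most outlying mice were added. Correlations carry permutation p-values from 100000 resamples.

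The models were tested on simulated data: the residuals of the real probes, with whole mice permuted, received known differences in 200 of 16896 probes over 10 draws. For the slope, 60.7% of probes changed by 0.05 per 100 days were recovered, 95% at 0.1 and 99.8% at 0.2. For old against young adult mice fed ad libitum, 81.3% were recovered at a difference of 0.5, and for the comparison of diets over adults 97.8%. The comparison of the sexes recovered 97.4% at 0.5. The interaction of diet with age recovered 47.5% at 0.5, 92.4% at 1 and 98.5% at 1.5. The comparison within juveniles recovered 23.4% at 0.5 and 92% at 1. The median draw called at most 2.5 unchanged probes in any of these comparisons. Single draws called many more, up to 853 for the slope, 2361 for old against young adult mice and 1944 for the interaction, because the probes of a mouse move together.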

Results

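Transcript levels in the thymus were compared between mice of different age, diet and sex. The thymus is the organ in which T lymphocytes mature, and in mice as in people it shrinks with age. The 67 mice comprised 40 fed ad libitum and 27 under calorie restriction, and 35 females and 32 males. Mice fed ad libitum were juvenile (17 to 44 days), young adult (169 to 194 days), middle-aged (472 to 499 days) or old (673 to 743 days), with 5 females and 5 males in each band. Restricted mice covered the 3 adult bands with 5 females each, and with 4, 5 and 3 males. The 3 old restricted males were all 673 days old, while the other old mice were 703 to 743 days old. Each mouse gave 2 arrays, A and B, with 16896 probes together, and levels are z-scores within an array. Pairs of mice correlated with a median r across probes of 0.942 on the A arrays and 0.954 on the B arrays, and at the lowest with 0.691 on both. Array medians lay between -0.16 and -0.02 on the A arrays and between -0.19 and 0.02 on the B arrays.

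The age comparison asked which transcripts moved along a straight line over the 40 mice fed ad libitum. Hmgn2, which encodes a nucleosome-binding protein, fell by 0.127 ± 0.027 z-score units per 100 days (SE, n = 40), from 0.55 ± 0.44 in juveniles to -0.36 ± 0.50 in old mice (SD, n = 10 each). H2az1, the histone variant H2A.Z, fell by 0.103 ± 0.022 per 100 days, and Tuba1b, an alpha-tubulin, fell by 0.117 ± 0.027. Ctsl, a cysteine protease with which the cortical epithelium prepares peptides for T cell selection, fell by 0.129 ± 0.030 per 100 days, from 0.73 ± 0.32 in juveniles to -0.19 ± 0.55 in old mice. Tspyl2, a nucleosome assembly protein, fell by 0.101 ± 0.030. The largest rises among genes were those of Fbxw24, an F-box protein, with 0.126 ± 0.031 per 100 days, and of Ccdc192 with 0.126 ± 0.027. Jag1, a ligand of Notch receptors, rose by 0.119 ± 0.030, from 1.93 ± 0.49 to 2.70 ± 0.58 in the brighter of its 2 probes (-0.009 ± 0.007 in the other), Pls1, an actin-bundling protein, by 0.118 ± 0.027 and Msantd1 by 0.115 ± 0.028. The adjusted p of these 10 genes lay between 0.0114 and 0.0265.

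Of the 48 measured proliferation genes, 9 fell with age, 2 rose and 37 did not pass. Stmn1, a microtubule-destabilising protein of dividing cells, fell by 0.090 ± 0.018 per 100 days and Hmgb2, a DNA-bending chromatin protein, by 0.094 ± 0.022. Rfc3, a subunit of the clamp loader of DNA replication, went the other way and rose by 0.077 ± 0.017. Adjusted over the list alone, 15 proliferation genes fell and 2 rose. As a group they were lower with age than other probes (camera, adjusted p = 2.06e-08), but with an estimated correlation the adjusted p = 0.352. Among 6 measured thymocyte genes 2 fell: Satb1, a chromatin organiser of developing T cells, by 0.068 ± 0.019, and Ets1, a transcription factor of lymphocytes, by 0.044 ± 0.013. Of 8 cortical epithelial genes, 2 fell, Ctsl and Il7, the survival cytokine of early thymocytes, which fell by 0.056 ± 0.019. Psmb11, the proteasome subunit found in cortical epithelium, had a slope of 0.026 ± 0.009 that did not pass (adjusted p = 0.053). Adjusted over the list alone, 4 cortical epithelial genes fell and 1 rose, and camera gave an adjusted p = 0.00531 with the preset correlation. With an estimated correlation the adjusted p = 0.352. Among 7 medullary epithelial genes 1 rose, Dclk1, a kinase used as a marker of tuft cells, by 0.029 ± 0.009.

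Of 67 cytosolic ribosomal protein genes, 15 fell, 1 rose and 51 did not pass, and adjusted over the list alone 41 fell and 1 rose. Rpl7 fell by 0.063 ± 0.017 per 100 days and Rpl15 by 0.062 ± 0.017, each with all their probes passing. The brightest probe of Rpl10 rose by 0.043 ± 0.011, but its other 3 probes had slopes of -0.049, -0.018 and -0.038 that did not pass, so the direction of Rpl10 is unclear. The mean over the ribosomal list was 0.66 ± 0.14 in juveniles, 0.58 ± 0.24 in young adults, 0.42 ± 0.37 in middle-aged and 0.36 ± 0.30 in old mice (SD, n = 10 each). Camera gave the list an adjusted p = 1.55e-24, and with an estimated correlation the adjusted p = 0.433. Of 35 heat shock and folding genes 4 fell and 31 did not pass, with camera at adjusted p = 1.6e-10 and, with an estimated correlation, adjusted p = 0.352. Ppia, a prolyl isomerase, fell by 0.094 ± 0.027, Hsp90b1, a chaperone of the endoplasmic reticulum, by 0.060 ± 0.017, Pdia3, a disulfide isomerase, by 0.048 ± 0.016 and Stip1, a co-chaperone, by 0.045 ± 0.014. In the list of the electron transport chain and ATP synthase, 2 of 59 genes fell and 1 rose. Atp5a1 fell by 0.066 ± 0.019 and Atp5g2 by 0.029 ± 0.009, while Atp5l rose by 0.053 ± 0.013 in its brighter probe and had -0.038 ± 0.014 in the other, which did not pass, all subunits of the ATP synthase. That list was lower as a group with camera at adjusted p = 0.000682, and with an estimated correlation the adjusted p = 0.588.

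**Figure D1:**
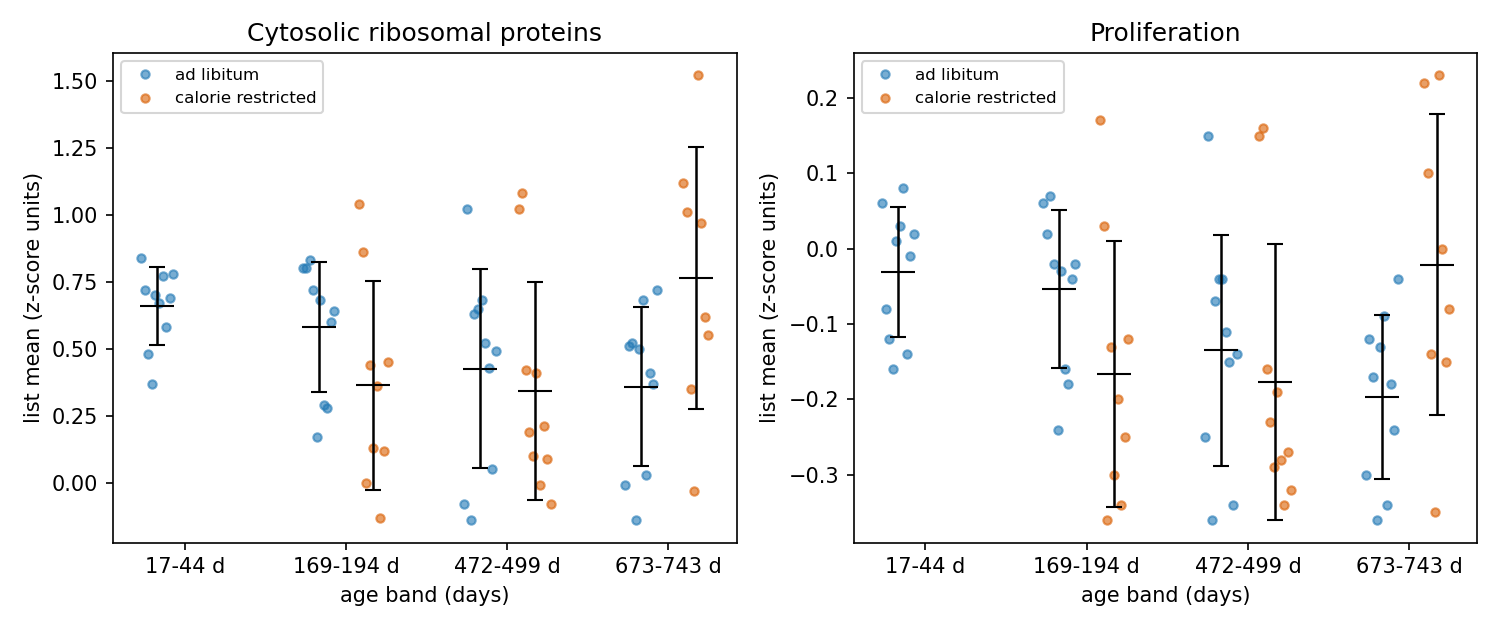
Mean z-score over the cytosolic ribosomal protein genes (left) and the proliferation genes (right) of each mouse, by age band in days and diet; each point is a mouse, and horizontal and vertical bars are the mean and SD of a group. In the left panel the mean of the mice fed ad libitum goes from 0.66 at 17 to 44 days to 0.36 at 673 to 743 days, and that of the restricted mice from 0.36 at 169 to 194 days to 0.76 at 673 to 743 days.

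Markers of other cells moved singly. Ighm, the heavy chain of immunoglobulin M and a marker of B cells, rose by 0.079 ± 0.025 per 100 days (adjusted p = 0.0341), from 0.29 ± 0.13 in juveniles to 0.65 ± 0.36, 0.62 ± 0.61 and 0.97 ± 0.58 in the later bands (SD, n = 10 each), and it was 1 of 3 measured B lineage genes to pass. Across the 40 mice Ighm correlated with age with r = 0.42 (permutation p = 0.007, Benjamini-Hochberg adjusted p = 0.0088 over 5 relations) and rho = 0.41 (permutation p = 0.0086), and with r = 0.45 without the 2 mice farthest in age from the median. Among the 34 mice numbered 13 to 67 r was 0.48 (permutation p = 0.0037) and rho 0.43 (permutation p = 0.012). These correlations restate the slope of Ighm in the same mice, or in part of them, and are not further evidence. Lgmn, a lysosomal protease of antigen-presenting cells, rose by 0.049 ± 0.015 and was the 1 gene of 13 to pass in the list of macrophages, dendritic cells and antigen presentation. Acta2, smooth muscle actin, fell by 0.085 ± 0.023 as 1 of 29 matrix and fibroblast genes counted by their brightest probe, and dimmer probes of Sparc (-0.072 ± 0.020) and Lamb1 (-0.044 ± 0.012) fell as well. Stat2, a transcription factor of interferon signalling, rose by 0.035 ± 0.012 as 1 of 8 interferon response genes. By limma, 0 of 7 adipocyte genes passed (2 at an unadjusted p under 0.05), 0 of 5 endothelial genes (0), 0 of 9 red blood cell genes (2), 0 of 3 muscle genes (0) and 0 of 10 apoptosis regulators (0), each counted by its brightest probe. Dimmer probes of the apoptosis regulators Diablo (-0.068 ± 0.020) and Mcl1 (-0.025 ± 0.009) did fall. Hba-a1, an alpha-globin, had a slope of 0.034 ± 0.018 and Agt, angiotensinogen, one of -0.047 ± 0.016 (adjusted p = 0.0506).

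Lysosomal genes split, with Lgmn and Laptm4a (0.025 ± 0.007 per 100 days) rising and Man2b1, an alpha-mannosidase, falling by 0.029 ± 0.010, and 22 of 25 not passing. In the glucocorticoid response list 2 of 13 genes fell: Fkbp5, a co-chaperone induced by glucocorticoids, by 0.045 ± 0.012, and Nr3c1, the glucocorticoid receptor, by 0.054 ± 0.016. Of 24 genes of oxidative stress and detoxification 3 rose: Cat, catalase, by 0.035 ± 0.010, Gpx3, a secreted glutathione peroxidase, by 0.048 ± 0.015, and Ephx1, an epoxide hydrolase, by 0.027 ± 0.009. Of 11 cholesterol synthesis genes 3 rose: Fdft1, squalene synthase, by 0.085 ± 0.021, Msmo1, a sterol oxidase, by 0.033 ± 0.010 in the brighter of its 2 probes (-0.003 ± 0.012 in the other), and Srebf1, a regulator of lipid synthesis, by 0.031 ± 0.010. Among probes for 7 sex-linked genes that for Eif2s3y, a Y-linked gene, fell by 0.045 ± 0.015, but it read -0.86 in females and -0.92 in males and so does not report the Y-linked transcript. For the slope, 5 of the 21 lists passed camera with the preset correlation, those of proliferation, cortical epithelium, ribosomal proteins, heat shock and electron transport, and 0 passed with an estimated correlation. Igf1, a growth factor, had a slope of 0.022 ± 0.009 (adjusted p = 0.116).

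**Figure D2:**
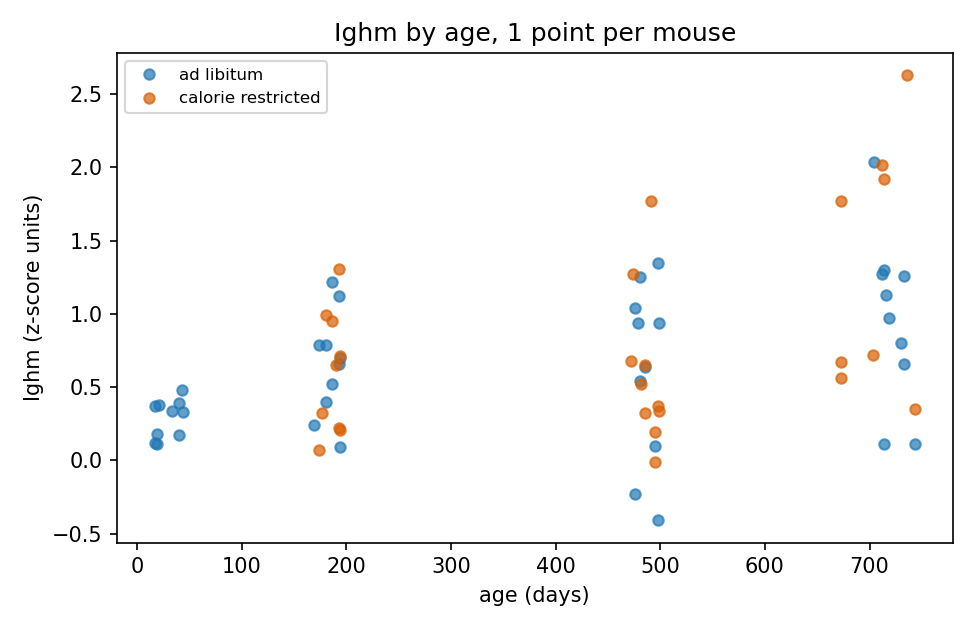
Level of Ighm in z-score units against age in days; each point is a mouse, blue for ad libitum and orange for calorie restricted. Mice of 17 to 44 days averaged 0.29 and mice fed ad libitum of 673 to 743 days averaged 0.97.

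By limma 2060 of 16896 probes passed for the slope, 1217 higher and 843 lower with age, and they hold 764 genes, 415 higher and 349 lower. On log2 of age 0 probes passed by limma (3590 at an unadjusted p under 0.05), and in adults alone 157 passed. Array weights gave 5151, 1 probe per gene 711, the first principal component as a covariate 94, leaving out mice 1 to 12 gave 1067 and a block for these mice 1322. Without mouse 67 the count was 3130, and it fell to 1165 without mouse 1, 1294 without mouse 13, 1036 without mouse 28, 1268 without mouse 42, 1039 without mouse 54 and 1315 without mouse 66. No single mouse ended the calls of Hmgn2, H2az1, Stmn1, Hmgb2, Tuba1b, Ctsl, Satb1, Rfc3, Jag1, Rpl7, Rpl10, Acta2, Fkbp5 or Fdft1. The call of Ighm ended without mouse 2, 27, 29, 54, 55 or 57, those of Ets1, Atp5a1 and Ppia without mouse 28, that of Nr3c1 without 28 or 54, that of Cat without 66, and those of Tspyl2 and Atp5g2 without 1, 13, 28 or 54. Lgmn lost its call without 1, 28, 29, 54, 55 or 66, Msmo1 without 1, 28, 54, 55, 57 or 66, and Srebf1 without 1, 27, 28, 55 or 66. Only the removal of 1 of the 40 mice fed ad libitum can change the slope. Of these 40 removals, 7 ended the call of Stip1, 8 that of Gpx3, 9 that of Dclk1, 12 that of Ephx1 and 15 that of Pdia3. The call of Eif2s3y ended in 16, that of Stat2 in 19, that of Il7 in 25 and that of Man2b1 in 26 of the 40. Calls of Psmb11 were brought in 10 and of Agt in 13.

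Between successive age bands no gene passed. From juvenile to young adult mice fed ad libitum, Tor1aip1, a protein of the nuclear envelope, differed by -0.324 ± 0.078 (SE), Psmg4, a proteasome assembly chaperone, by -0.300 ± 0.081, Dnaaf5 by 0.311 ± 0.094 and Cobl, an actin nucleator, by 0.223 ± 0.069 (n = 10 and 10). Top2a, the topoisomerase of dividing cells, stood at 0.26 ± 0.11 in juveniles and 0.09 ± 0.16 in young adults (SD), and Mt1, a metallothionein, at 1.28 ± 0.29 and 1.00 ± 0.19. Rpl8 differed by -0.182 ± 0.079, and the ribosomal list had a median difference of -0.086 (camera, adjusted p = 0.000536; adjusted p = 0.77 with an estimated correlation). By limma 0 probes passed (lowest adjusted p = 0.999), 736 had an unadjusted p under 0.05, and array weights gave 594. Igf1 differed by 0.022 ± 0.081, and by -0.034 against juveniles of 33 to 44 days alone.

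From young adult to middle-aged mice Gcnt3, a mucin glycosyltransferase, differed by 0.536 ± 0.130, Fdft1 by 0.456 ± 0.159, C1qc, a complement component of macrophages, by -0.243 ± 0.075 and Aurka, a mitotic kinase, by -0.193 ± 0.070 (SE, n = 10 and 10). Igf1 differed by -0.020 ± 0.081, and by 0.008 with median centring. By limma 0 probes passed (lowest adjusted p = 0.415), with 1674 at an unadjusted p under 0.05 and 393 passing with array weights. Proliferation genes were lower in middle-aged mice as a group with a median of -0.083 (camera, adjusted p = 0.0178) and so were ribosomal genes with -0.185 (adjusted p = 3.38e-06). With an estimated correlation both had an adjusted p = 0.854. From middle-aged to old mice Rbm5, a splicing factor, differed by 0.349 ± 0.084, Bgn, a matrix proteoglycan, by 0.193 ± 0.068, Dhcr7, the last enzyme of cholesterol synthesis, by -0.490 ± 0.149 and Cox7b, a subunit of cytochrome oxidase, by -0.282 ± 0.086. By limma 0 probes passed (lowest adjusted p = 0.588), 1276 had an unadjusted p under 0.05 and 406 passed with array weights. Proliferation (median -0.050, camera adjusted p = 0.0373), electron transport (-0.052, adjusted p = 0.031), ribosomal (-0.061, adjusted p = 0.0373) and heat shock genes (-0.088, adjusted p = 0.00444) were lower as groups. With an estimated correlation all 4 had an adjusted p = 0.938, and with 1 probe per gene 0 lists passed.

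Over the whole adult span the 10 old and 10 young adult mice fed ad libitum differed in Ednrb, an endothelin receptor, by 0.512 ± 0.124, in Ccnd3, the D-type cyclin of developing thymocytes, by -0.342 ± 0.082 and in Ctsl by -0.751 ± 0.267 (SE). None of them passed, with adjusted p of 0.0967 for Ednrb and Ccnd3 and 0.149 for Ctsl. Cat differed by 0.253 ± 0.079 and Igf1 by 0.156 ± 0.081. By limma 0 probes passed and 2829 had an unadjusted p under 0.05. A block for the cycle of running numbers gave 452, fits on the compared groups alone 132 and array weights 5067, and leaving out mouse 67 gave 483 and mouse 26 gave 1. As groups, proliferation genes (median -0.125, camera adjusted p = 1.05e-05), electron transport genes (-0.103, adjusted p = 0.000396), ribosomal genes (-0.228, adjusted p = 1.07e-09) and heat shock genes (-0.183, adjusted p = 7.63e-06) were lower in old mice. With an estimated correlation their adjusted p was 0.567, 0.827, 0.827 and 0.643.

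The next comparison asked whether the change from young adult to old mice differed between diets. Hmgn2 stood at 0.32 ± 0.45 in young adult and -0.36 ± 0.50 in old mice fed ad libitum (SD, n = 10 each), and at -0.29 ± 0.74 in young adult (n = 9) and 0.38 ± 0.63 in old restricted mice (n = 8). The difference between its changes was 1.378 ± 0.390 (SE, adjusted p = 0.0303). Higher by the same measure were Tuba1b with 1.309 ± 0.373, H2az1 with 1.270 ± 0.338, Ctsl with 1.217 ± 0.399 and Sirpa, an inhibitory receptor of myeloid cells, with 1.309 ± 0.392. The Sirpa probe was dim, far below the array medians. It stood at -2.387 ± 0.564 over old restricted and young adult ad libitum mice and at -3.015 ± 0.749 over the others compared (SD, n = 18 and 19). The largest differences downward were those of Fbxw24 with -1.555 ± 0.355, Msantd1 with -1.405 ± 0.316, Jag1 with -1.339 ± 0.337, Ccdc192 with -1.335 ± 0.344 and Nlrp9b, an inflammasome receptor, with -1.308 ± 0.319 in the brighter of its 2 probes (-0.204 ± 0.154 in the other). Jag1 stood at 1.90 ± 0.48 in young adult and 2.70 ± 0.58 in old mice fed ad libitum, and at 2.47 ± 0.66 and 2.04 ± 0.69 in restricted mice. Its other probe had an interaction of 0.105 ± 0.084 and did not pass. The test is of the difference between both changes, since neither change passed within its own diet. Hmgn2, Tuba1b, H2az1, Ctsl, Fbxw24, Msantd1, Jag1 and Ccdc192 were also among the genes with the largest slopes over age. Both results use the same young adult and old mice fed ad libitum, so they are not independent.

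Of 48 proliferation genes 8 were higher and 1 lower in this interaction, and adjusted over the list alone 14 were higher and 1 lower. Mcm3, a subunit of the replicative helicase, had 0.704 ± 0.169, Hmgb2 1.161 ± 0.295 and Plk1, a mitotic kinase, 0.527 ± 0.154. The list had a median of 0.258 (camera, adjusted p = 4.68e-07), and with an estimated correlation the adjusted p = 0.305. Of 67 ribosomal genes 7 were higher, and adjusted over the list alone 43 were higher and 1 lower. Rpl7 had 0.890 ± 0.270, Rpl23a 0.750 ± 0.224 and Rpl35 0.609 ± 0.172, and the list median was 0.658 (camera, adjusted p = 7.35e-26; with an estimated correlation, adjusted p = 0.329). Of 35 heat shock and folding genes 5 were higher, and adjusted over the list alone 8. They include Ppia with 1.155 ± 0.376, Hsp90b1 with 0.850 ± 0.232, Calr, a chaperone of glycoproteins, with 0.611 ± 0.206 and Cct8, a chaperonin subunit, with 0.437 ± 0.132. That list had a median of 0.483 (camera, adjusted p = 3.65e-11), and with an estimated correlation the adjusted p = 0.305. Electron transport genes had a median of 0.167 (camera, adjusted p = 0.000487; with an estimated correlation, adjusted p = 0.491), although the 1 of 59 genes that passed, Atp5l, was lower with -0.513 ± 0.170 in its brighter probe (0.490 ± 0.212 in the other, not passing). Lysosomal genes had a median of 0.172 (camera, adjusted p = 0.0299; with an estimated correlation, adjusted p = 0.329), with Man2b1 higher by 0.409 ± 0.109, Lgmn lower with -0.493 ± 0.165 and 23 of 25 not passing.

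The other lists did not pass camera for this interaction. Nr3c1 (0.778 ± 0.234) and Nfkbia, an inhibitor of NF-kappaB (0.456 ± 0.140), were higher among 13 glucocorticoid response genes. Txn1, thioredoxin, was higher with 0.49 ± 0.15 and Gpx3 lower with -0.576 ± 0.185 among 24 genes of oxidative stress. Acta2 (0.864 ± 0.266) and Vim, vimentin (0.283 ± 0.090), were higher among 29 matrix genes. Slc4a1, the anion exchanger of red cells, was higher with 0.438 ± 0.127 as 1 of 9 red blood cell genes, and Igtp, a GTPase induced by interferon, with 0.538 ± 0.171 as 1 of 8 interferon genes. Lower were Dclk1 with -0.374 ± 0.124 as 1 of 7 medullary genes, Msmo1 with -0.499 ± 0.141 as 1 of 11 cholesterol genes, and Cflar, an inhibitor of caspase activation, with -0.538 ± 0.175 as 1 of 10 apoptosis regulators. Ctsl was the 1 cortical epithelial gene of 8, Lgmn the 1 antigen presentation gene of 13, and of the 7 sex-linked genes the probe for Eif2s3y was higher with 0.642 ± 0.206, although it does not separate the sexes. By limma 0 of 6 thymocyte genes passed (1 at an unadjusted p under 0.05), 0 of 7 adipocyte genes (2), 0 of 3 B lineage genes (0), 0 of 5 endothelial genes (0) and 0 of 3 muscle genes (0), each counted by its brightest probe. A dimmer probe of Sdc1, a plasma cell marker among the B lineage genes, was higher with 0.291 ± 0.095 (adjusted p = 0.0436). Ets1 had 0.376 ± 0.152 (adjusted p = 0.0869) and Igf1 -0.204 ± 0.121 (adjusted p = 0.255).

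By limma 1696 of 16896 probes passed for this interaction, 722 higher and 974 lower, and 4991 had an unadjusted p under 0.05. They hold 611 genes, 315 higher and 296 lower. The count was 0 with exact age within bands as a covariate (3109 at an unadjusted p under 0.05) and 0 with the first principal component as a covariate (2224), 517 on the compared groups alone, 995 with a block for mice 1 to 12, 404 with 1 probe per gene, 615 without the 3 most outlying mice, 3527 with the cycle of running numbers as a block and 6346 with array weights. Without mouse 11, 17 or 49 no probe passed, so no gene named for this interaction held its call in every removal. The count fell to 166 without mouse 39, 261 without 44, 338 without 5, 339 without 28, 365 without 50, 473 without 12, 506 without 60, 666 without 19, 735 without 31 or 32, 776 without 6, 919 without 54 or 55 and 1088 without 59. It rose to 2545 without mouse 33, 2723 without 46, 2778 without 67, 2932 without 4, 3694 without 3, 3704 without 25 and 3745 without 26. The calls of Fbxw24, Msantd1, Jag1, Nlrp9b and Mcm3 ended in 3 of 67 removals and that of Calr in 27. The contrast compares only the 19 young adult and 18 old mice, and the other mice enter it through the shared spread alone.

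Within restricted mice alone the 8 old and 9 young adult animals differed in Ighm by 0.679 ± 0.249, with 1.33 ± 0.85 in old and 0.60 ± 0.43 in young adult mice (SD). Mcm3 differed by 0.376 ± 0.126, Hsp90b1 by 0.515 ± 0.172, Igtp by 0.393 ± 0.127 and Eif4e, the cap-binding protein of translation, by 0.318 ± 0.083 (SE). Downward, Prim2, a primase subunit, differed by -0.323 ± 0.101, Msh4, a meiotic mismatch repair protein, by -0.538 ± 0.169 and Stxbp6, a syntaxin-binding protein, by -0.184 ± 0.058. In limma 0 probes passed (lowest adjusted p = 0.266), 2805 had an unadjusted p under 0.05 and 2627 passed with array weights. As groups, ribosomal genes (median 0.424, camera adjusted p = 7.35e-34), heat shock genes (0.272, adjusted p = 1.98e-12), proliferation genes (0.141, adjusted p = 9.14e-06), genes of macrophages, dendritic cells and antigen presentation (0.179, adjusted p = 0.00511), electron transport genes (0.058, adjusted p = 0.0112) and lysosomal genes (0.094, adjusted p = 0.0112) were higher in old mice. With an estimated correlation the adjusted p was 0.232, 0.213, 0.232, 0.213, 0.563 and 0.232 in the same order. Igf1 differed by -0.048 ± 0.090, by 0.008 with array weights and by 0.061 with the first principal component as a covariate.

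The diet comparison asked how restricted mice differed from mice fed ad libitum. Over the 3 adult bands, with 27 restricted mice and 30 fed ad libitum, the differences were small. Gpx3 differed by 0.211 ± 0.074 (SE), Lpl, lipoprotein lipase, by 0.136 ± 0.049, Hba-a1 by 0.269 ± 0.121 and Igf1 by 0.025 ± 0.048. Idi1, an isomerase of sterol synthesis, differed by -0.137 ± 0.038, Ptges, a prostaglandin E synthase, by -0.147 ± 0.038 and Ap1s1, a clathrin adaptor subunit, by -0.139 ± 0.034. Limma passed 0 probes (lowest adjusted p = 0.178) and 1038 had an unadjusted p under 0.05. Array weights gave 2, the first principal component as a covariate 5, and leaving out mouse 45 gave 1. Red blood cell genes (median 0.206, camera adjusted p = 1.34e-09), adipocyte genes (0.136, adjusted p = 0.00534), electron transport genes (0.048, adjusted p = 0.000172), ribosomal genes (0.042, adjusted p = 0.00534), heat shock genes (0.042, adjusted p = 0.000631) and genes of oxidative stress (0.025, adjusted p = 0.0288) were higher as groups under restriction. With an estimated correlation the adjusted p was 0.477, 0.477, 0.659, 0.747, 0.659 and 0.659 in the same order. With 1 probe per gene 2 instead of 6 lists passed.

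At 169 to 194 days 1 probe was higher in the 9 restricted than in the 10 ad libitum mice, probe 7320, which has no symbol (0.409 ± 0.076, adjusted p = 0.0206). Gpx3 differed by 0.504 ± 0.127, Lpl by 0.225 ± 0.084, Ccnd3 by -0.370 ± 0.084, Kpna1, a nuclear import adaptor, by -0.288 ± 0.074 and Hmgb2 by -0.535 ± 0.204 (SE), and none of these passed. In all, 1621 probes had an unadjusted p under 0.05. The count was 0 with quantile normalisation, median and deviation scaling, 1 probe per gene or the compared groups alone, 2 without mice 1 to 12, 4 with the first principal component as a covariate and 4792 with array weights. It was also 0 without any of mice 3, 4, 17, 31, 32, 33, 34, 45, 46, 50 and 60. Thymocyte genes (median -0.139, camera adjusted p = 0.0207), proliferation genes (-0.106, adjusted p = 0.000139), ribosomal genes (-0.235, adjusted p = 4.52e-13) and heat shock genes (-0.093, adjusted p = 0.000962) were lower as groups, and adipocyte genes (0.118, adjusted p = 0.011) and red blood cell genes (0.229, adjusted p = 0.000962) higher. The adjusted p with an estimated correlation was 0.192, 0.593, 0.593, 0.629, 0.35 and 0.593 in the same order. Adjusted over the list alone 2 of 7 adipocyte genes were higher. The red blood cell list mean differed by 0.23, and by 0.15 without mouse 3, which stood at 0.87.

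At 472 to 499 days (10 mice per diet) Arpp19, a regulator of mitotic phosphatase, differed by 0.241 ± 0.067, Hba-a1 by 0.508 ± 0.201, Slc2a8, a glucose transporter, by -0.209 ± 0.061 and Igf1 by 0.157 ± 0.081 (SE). In limma 0 probes passed (lowest adjusted p = 0.871), 885 had an unadjusted p under 0.05 and 1237 passed with array weights. Red blood cell genes were higher as a group (median 0.339, camera adjusted p = 2.72e-06) and ribosomal genes lower (-0.088, adjusted p = 0.00776), and with an estimated correlation both had an adjusted p = 0.821. With 1 probe per gene 0 lists passed at this age. Of the 10 restricted mice, 3 had high red blood cell means, mouse 7 with 1.91 (Hba-a1 at 3.13), mouse 61 with 0.89 and mouse 8 with 0.79, and the other 7 lay between -0.22 and 0.29. The difference in the list mean was 0.28, and 0.10 without mouse 7. At 673 to 743 days the 8 restricted mice differed from the 10 ad libitum mice in Mcm3 by 0.446 ± 0.122, in Kpna2, a nuclear import adaptor, by 0.408 ± 0.099, in Hsp90b1 by 0.588 ± 0.168, in Nr3c1 by 0.555 ± 0.169 and in Kif1b, a kinesin, by -0.494 ± 0.128. All of these had an adjusted p of 0.0819 and none passed. Limma passed 0 probes and 4895 had an unadjusted p under 0.05. The count was 2708 with the cycle of running numbers as a block, 3435 with array weights, and 1 with median centring, with median and deviation scaling or with the running number. Without single mice it was 3969 (mouse 25), 3725 (26), 1717 (67) and 1 (8). Ribosomal genes (median 0.412, camera adjusted p = 5.84e-24), heat shock genes (0.351, adjusted p = 1.09e-12), electron transport genes (0.168, adjusted p = 1.47e-07), proliferation genes (0.187, adjusted p = 5.58e-06), lysosomal genes (0.157, adjusted p = 0.0157) and matrix genes (0.118, adjusted p = 0.0476) were higher as groups. The adjusted p with an estimated correlation was 0.366 for electron transport genes and 0.287 for the other 5 lists. Adjusted over the list alone 29 of 67 ribosomal, 5 of 35 heat shock and 3 of 48 proliferation genes were higher.

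Females and males were compared over all ages and diets. Xist, the RNA that coats the inactive X chromosome, was higher in females by 0.525 ± 0.051 (SE, adjusted p = 1.99e-10), with -0.72 ± 0.24 in 35 females and -1.24 ± 0.20 in 32 males (SD). Female mouse 30 had an Xist level of -1.6, below the male mean, and male mouse 47 one of -0.86. The other measured sex-linked genes did not pass. Uty, a Y-linked gene, stood at -0.83 ± 0.27 in females and -0.78 ± 0.26 in males, and Eif2s3y, also Y-linked, at -0.86 ± 0.30 and -0.92 ± 0.38, so neither probe separated the sexes. Differences were -0.072 ± 0.033 for Eif2s3x, 0.087 ± 0.072 for Ddx3x, -0.030 ± 0.052 for Kdm6a and -0.010 ± 0.044 for Kdm5c. Ighm differed by 0.298 ± 0.124 and Pdgfra, a fibroblast receptor, by -0.136 ± 0.050, and neither passed.

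**Figure D3:**
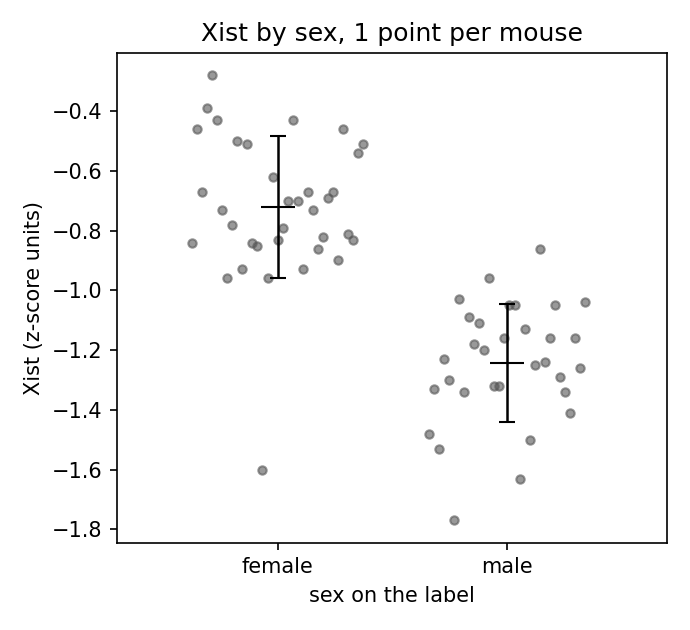
Level of Xist in z-score units in the females and males given by the labels; each point is a mouse, and horizontal and vertical bars are the mean and SD. The means are -0.721 in 35 females and -1.243 in 32 males, and 1 female lies at -1.6.

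Xist was the 1 probe that passed by limma for sex, and 294 probes had an unadjusted p under 0.05. The count was 0 without the dimmest 25% of probes, 2 with array weights and 2 without mouse 39. The sex-linked list passed camera (median 0.018, adjusted p = 0.0112), and with an estimated correlation the adjusted p = 0.056. It mixes X-linked and Y-linked genes, and Xist was its 1 passing gene, so the result need not be a shift of the whole list. Red blood cell genes were lower in females as a group (median -0.144, camera adjusted p = 5.3e-08), and ribosomal genes (0.10, adjusted p = 6.46e-18), electron transport genes (0.029, adjusted p = 0.00357) and heat shock genes (0.042, adjusted p = 0.00357) higher. The adjusted p with an estimated correlation was 0.507 for red blood cell genes and 0.569 for the other 3 lists. The highest red blood cell list means were those of single males: mouse 7 with 1.91, 61 with 0.89, 3 with 0.87, 54 with 0.83 and 11 with 0.80. Among females mouse 8 reached 0.79. How far the difference between the sexes depends on single mice was not tested.

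Whether the sexes differed in their response to age, maturation or diet was tested as interactions, each female minus male. For ageing from young adult to old under ad libitum feeding, Zc3h7a differed by 0.412 ± 0.124 and Slc6a8, the creatine transporter, by -0.348 ± 0.111 (SE, n = 5 per sex and age). Red blood cell genes had a median of -0.376 (camera, adjusted p = 0.00728; with an estimated correlation, adjusted p = 0.788). With 1 probe per gene 0 lists passed for this interaction. Old male mouse 54 had a red blood cell mean of 0.83, and the other old males fed ad libitum lay between -0.26 and 0.42. For maturation from juvenile to young adult, Aox3, an aldehyde oxidase, differed by -0.406 ± 0.119 and Acp1, a low-weight tyrosine phosphatase, by 0.486 ± 0.158. Ribosomal genes had a median of 0.161 (camera, adjusted p = 0.000111) and heat shock genes of 0.128 (adjusted p = 0.00957), and with an estimated correlation both had an adjusted p = 0.816. For diet over adults Adipor1, an adiponectin receptor, differed by 0.292 ± 0.103 and Mllt10 by 0.328 ± 0.106, and Pqlc3 by -0.369 ± 0.104, Ccdc14 by -0.217 ± 0.073 and Bex1 by -0.205 ± 0.070. Proliferation genes (median -0.115, camera adjusted p = 4.29e-06), red blood cell genes (-0.201, adjusted p = 0.00123), ribosomal genes (-0.239, adjusted p = 2.57e-15) and heat shock genes (-0.128, adjusted p = 2.17e-06) were lower as groups. The adjusted p with an estimated correlation was 0.555, 0.593, 0.57 and 0.57. The red blood cell value includes mouse 7, a restricted male with a list mean of 1.91. These lists were not retested without single mice. In limma 0 probes passed for each of the 3 interactions, and 233, 291 and 513 had an unadjusted p under 0.05 in the order given. Each alternative fit gave 0 as well.

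Among the 10 juveniles, 5 were 17 to 21 and 5 were 33 to 44 days old, on either side of weaning. Fastkd1, a mitochondrial RNA-binding protein, differed by 0.545 ± 0.101 between the older and the younger mice and Senp8, a protease of the NEDD8 system, by 0.709 ± 0.207, while Hsdl2, a peroxisomal dehydrogenase, differed by -0.334 ± 0.106 (SE, n = 5 and 5). Limma passed 0 probes, 116 had an unadjusted p under 0.05, and array weights gave 1. Red blood cell genes (median -0.101, camera adjusted p = 2.74e-05) and heat shock genes (-0.039, adjusted p = 0.0387) were lower as groups in the older juveniles. The adjusted p with an estimated correlation was 0.811 and 0.875, and with 1 probe per gene 0 lists passed.

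A single direction of variation ran through all mice. The first principal component of all probes took 41.2% of the variance, against 9.8% and 7.86% for the next, and 21.6% of it lay between the 14 groups (permutation p = 0.36). Ribosomal probes followed it with a median r of 0.93 across mice, heat shock probes with 0.81, electron transport probes with 0.73, cortical epithelial probes with 0.69 and proliferation probes with 0.61. Medullary epithelial probes had -0.51, the 3 muscle probes -0.47 and cholesterol synthesis probes -0.28. In the 40 mice fed ad libitum it correlated with age with r = -0.43 (permutation p = 0.0066, Benjamini-Hochberg adjusted p = 0.0088 over 5 relations) and rho = -0.42 (permutation p = 0.0081), and with r = -0.37 without the 2 mice farthest in age from the median. Among the 34 mice numbered 13 to 67 r was -0.42 (permutation p = 0.014) and rho -0.44 (permutation p = 0.0099). Its mean was 7.72 ± 11.56 in juveniles and -10.75 ± 16.49 in old mice fed ad libitum (SD, n = 10 each), and 14.66 ± 29.65 in old restricted mice (n = 8).

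**Figure D4:**
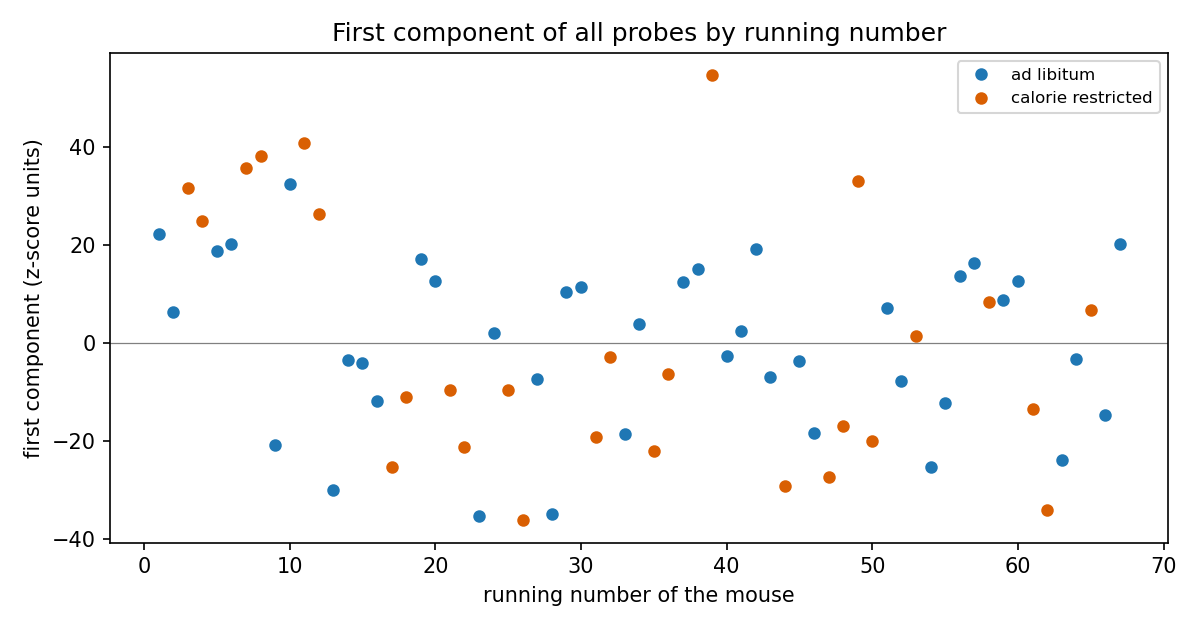
First principal component of all probes, in z-score units, against the running number of the mouse on the labels; each point is a mouse, blue for ad libitum and orange for calorie restricted. All mice numbered 1 to 12 except mouse 9 lie above 0, among them mouse 3 at 31.6 and mouse 7 at 35.8.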

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

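Comparisons with other splits of the mice were fixed before the results were seen, and the tests on running numbers, on mouse 39, on the first principal component and on cell types and the comparison of splits by unadjusted p were chosen afterwards. Within groups of 4 or 5 mice, a mouse was singled out where its gap to the nearest other mouse exceeded Dixon's 95% value. Of 91 groups over 7 measures, 12 had such a mouse, and chance alone gives about 1 in 20. Mouse 3, a young adult restricted male, stood out with 31.6 on the first component, 1.04 for the ribosomal mean, 0.87 for the red blood cell mean, 0.95 for Ighm and 1.55 for Hba-a1. Mouse 8, a middle-aged restricted female, had a red blood cell mean of 0.79 and Hba-a1 at 1.46, and mouse 6, a young adult female fed ad libitum, had 0.48 and 1.15. Mouse 7, a middle-aged restricted male, reached 35.8 on the first component. Mouse 46, a young adult female fed ad libitum, had a proliferation mean of -0.18, and mouse 51, a middle-aged male fed ad libitum, a red blood cell mean of 0.3.

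Effects that differed between groups by their interaction were the 1696 probes for diet with age, a count that lay between 0 without mouse 11, 17 or 49 and 3745 without mouse 26. The list medians for diet with age were 0.258 for proliferation, 0.167 for electron transport, 0.658 for ribosomal, 0.483 for heat shock and 0.172 for lysosomal genes. Between the sexes the red blood cell genes differed by -0.376 in their change with age. Ribosomal genes differed by 0.161 and heat shock genes by 0.128 in maturation. Under diet the sexes differed by -0.115 in proliferation, -0.201 in red blood cell, -0.239 in ribosomal and -0.128 in heat shock genes. None of these list differences passed with an estimated correlation. These lists were not retested without single mice, and single males such as 7 (1.91) and 54 (0.83) had high red blood cell means.

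The slope with age in mice fed ad libitum called 2060 probes, between 1036 without mouse 28 and 3130 without mouse 67. Of 100 splits of the mice 1, the real one, called as many, and the next called 1830. At an unadjusted p under 0.05, 2 had as many probes (5278 in the other against 4668). The real count is thus rare among splits that treat single mice as exchangeable. A random split can come this close to the real count because the probes of a mouse move together. Residuals of the first component within groups correlated from one running number to the next (r = 0.41), so mice resembled their neighbours. Chance among such mice is therefore not excluded. All of mice 1 to 12 except mouse 9 lie above 0 on the first component. Without these 12 the 2060 probes kept a median 0.92 of their slope, so its size does not rest on that stretch alone. The 12 include no old mouse fed ad libitum, and 34 of the 40 mice stayed in the fit. A small loss was therefore likely in any case. Of the 2060 probes, 2046 passed with the cycle of running numbers as a block and 1624 with the running number as a covariate. Within each cycle the mice fed ad libitum run from juvenile to old, so neither fit can separate age from a drift within cycles. With the first component as a covariate the 2060 probes kept 0.43, and the median slope went from 0.049 with an SE of 0.014 to 0.020 with an SE of 0.011. The component itself moves with age, so ageing and an unnamed technical factor that ages share may both lie behind the calls and cannot be told apart here.

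Of 100 splits for the interaction of diet with age only the real 1 called any probe, the highest other calling 0, and 2 had as many at an unadjusted p under 0.05 (5244 in the other against 4991). In simulated data 10 permutations of whole mice called up to 1944 unchanged probes, with a median of 0. Those draws also carried 200 changed probes, which eases the Benjamini-Hochberg threshold, so their counts cannot be set directly against the real 1696. The real count is thus rare among splits that treat single mice as exchangeable, but chance among mice that resemble their neighbours is not excluded. Mouse 39 is the old restricted female with the lowest median correlation with the other mice (0.86). Without it the 1696 probes kept a median 0.91 of their difference, so the size of the difference does not rest on mouse 39 alone. It is 1 of 5 old restricted females and carries only part of their mean, so a small loss was likely in any case. The count did rest on single mice, with 166 probes without mouse 39 and 0 without mouse 11, 17 or 49. Without mice 1 to 12 the 1696 probes kept 1.03 of their difference, so its size does not rest on that stretch alone. Of the restricted mice in it, young adults 3 and 4 (31.6 and 24.8) and old mice 11 and 12 (40.7 and 26.4) all lay high on the component. They stand on opposite sides of the contrast, so a small change was likely in any case. With the first component as a covariate they kept 0.39, with a median size of 0.226 and an SE of 0.118 against 0.595 and 0.179, and 0 probes passed because the size shrank more than the error. A response to restriction that differs with age and a chance run of old restricted mice along the component may each account for it, and exact age, at which 0 probes passed, stays open because the 3 old restricted males were all 673 days old.

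The first component took 41.2% of the variance, and 21.6% of it lay between the 14 groups (permutation p = 0.36). Computed from the A and the B arrays apart, it correlated over mice with r = 0.95 (rho = 0.97; both permutation p = 1e-05, the smallest the resamples can give; r = 0.95 without the 2 farthest mice), which argues against noise of single arrays. Of 9 lists of other cell types, 7 correlated with it positively and 1, medullary epithelium, negatively (r = -0.68). The test assumed that a lower share of thymocytes raises all other types alike, and the 7 positive lists go against that simple form. Thymocyte probes also followed the component (median r = 0.45), and several lists hold few genes. A change in the share of thymocytes beside the component can therefore not be judged. From one running number to the next its residuals within groups correlated with r = 0.41 (permutation p = 0.00015), which is consistent with a factor tied to the order of the mice. Whether that factor lies in the tissue, such as dissection or time to freezing, or in the labelling was not tested.

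For the other comparisons the mice were also split at random into groups of the same sizes, 100 splits each. Splits as large as the real one numbered 2 for diet in young adults, where the real count was 1 probe and the highest other 1538, and 3 for sex, where the real count was 1 and the highest other 2209, but at an unadjusted p under 0.05, 8 and 77 of the 100 splits had as many probes. Counts of 1 probe or more were thus rare among the splits, but chance is not excluded for either comparison as a whole. For diet in young adults it is not excluded for the 1 probe either. The 16 comparisons were split without correction for their number, and that call ended in 11 of 67 removals of single mice. All 11 were among the 19 young adult mice compared. For the 12 comparisons with a real count of 0, 100 of 100 splits had to give as many, which decides nothing about chance. At an unadjusted p under 0.05, 2 of 100 splits had as many for old minus young adult mice fed ad libitum, and 7 to 95 for the other 11. The highest other counts were 0 from juvenile to young adult and from young adult to middle-aged mice, 19 from middle-aged to old, 2 from young adult to old, 6703 for the same span under restriction, 4537 for diet over adults, 1169 for diet at middle age, 4402 for diet at old age, 0 for sex with age and for sex with maturation, 2445 for sex with diet and 1794 within juveniles. Such high counts can arise in random splits because the probes of a mouse move together.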

How the results depend on the processing

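All alternatives were fixed before the results were seen except leaving out mice 1 to 12, taking them as a block, the first component as a covariate and leaving out the 3 outlying mice (7, 9 and 39). A trended robust prior, no moderation, adjustment per table and leaving out mouse 27 each moved none of the 16 counts by more than 1.5 times. An offset before a logarithm could not be run on z-scores, a filter on complete probes changed nothing because no value is missing, and the fits on compared groups and on exact age could not be made for the slope and the juveniles, nor the block of mice 1 to 12 for juveniles. No paired analysis was possible because each running number names 1 mouse; the 5 cycles in which the numbers run through the groups were fitted as a block instead. Where no cause is given, the cause was not tested.

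Quantile normalisation gave 0 probes for diet in young adults (1 as reported), and median and deviation scaling 0 as well. Median centring and median and deviation scaling gave 1 for diet in old mice (0 as reported), as did the running number. Without the dimmest 25% of probes the sex count was 0, since Xist is among them. The cycle block gave 452 for old minus young adult mice fed ad libitum (0 as reported), 2708 for diet in old mice and 3527 for the interaction of diet with age (1696 as reported). The compared groups alone gave 132 for old minus young adult, 0 for diet in young adults and 517 for the interaction, and exact age gave 0 for it. With 1 probe per gene, and so fewer probes tested, diet in young adults gave 0, the interaction 404 and the slope 711 (2060 as reported), and 35 instead of 61 list tests passed. For old minus middle-aged mice, diet at middle age, sex with age and juveniles 0 list tests then passed. Diet in adults kept 2 of 6, sex 2 of 5, the slope 3 of 5, and the interaction of diet with age again had 5. With estimated correlations 0 list tests passed. Adults alone, with fewer mice, gave 157 for the slope, and log2 of age 0.

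Array weights, which count mice near their group mean more, gave 594 from juvenile to young adult, 393 to middle-aged and 406 to old, 5067 for old minus young adult, 2627 for the same under restriction, 2 for diet in adults, 4792 in young adults, 1237 in middle-aged and 3435 in old mice, 2 for sex, 6346 for the interaction, 5151 for the slope and 1 within juveniles. Without mice 1 to 12 diet in young adults gave 2 and the slope 1067. The block for mice 1 to 12 gave 995 for the interaction and 1322 for the slope. The first component as a covariate gave 5 for diet in adults, 4 in young adults, 0 for the interaction and 94 for the slope. Without the 3 outlying mice the interaction gave 615.

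Leaving out each mouse in turn gave 1036 to 3130 for the slope, 0 to 3745 for the interaction, 0 to 483 for old minus young adult fed ad libitum, 0 to 3969 for diet in old mice, 0 to 1 for diet in young adults and in adults, 1 to 2 for sex, and 0 throughout for the other 9.

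Signs turned only for genes that did not pass. Igf1 from young adult to middle age (-0.020 as reported) was 0.008 with median centring and with median and deviation scaling, 0.033 with array weights, 0.026 without mice 1 to 12 and 0.028 without the outlying mice. Igf1 from young adult to old under restriction was 0.008 with array weights and 0.061 with the first component, and from juvenile to young adult -0.034 with juveniles of 33 to 44 days. Kdm5c between the sexes was 0.012 with exact age and -0.028 to 0.014 without single mice, and Eif2s3y -0.048 with array weights. The medians of all 61 passing lists kept their sign under quantile normalisation, median centring and deviation scaling. Signal over background is not known, so a difference that did not pass may lie below what these arrays detect.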

Other observations

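The tests below on cell type lists were chosen after the first component had been seen. The means of 9 lists of other cell types were set against that component over the 67 mice. The mean of the matrix and fibroblast list had r = 0.95 (rho = 0.95), although its single probes had a median r of 0.35, below the 0.69 of cortical epithelium and the 0.58 of macrophages and antigen presentation. Next came the means of cortical epithelium with r = 0.90 (rho = 0.92), genes of macrophages, dendritic cells and antigen presentation with r = 0.83 (rho = 0.85), B lineage genes with r = 0.67 (rho = 0.70) and adipocyte genes with r = 0.65 (rho = 0.63). Medullary epithelium ran the other way with r = -0.68 (rho = -0.67). All of these had a permutation p = 1e-05, the smallest the resamples can give, and a Benjamini-Hochberg adjusted p = 1.5e-05 over the 9 lists. The component is computed from all probes, those of these lists included, and random sets of probes were not run. Such p-values therefore do not tell a cell type from any other set of probes. Red blood cell genes had r = 0.47 (permutation p = 5e-05; rho = 0.50, permutation p = 2e-05), endothelial genes r = 0.42 (permutation p = 0.00039; rho = 0.45, permutation p = 0.00021), and muscle genes r = -0.22 (permutation p = 0.068; rho = -0.13, permutation p = 0.29). Without the 2 mice farthest on the component r was 0.95, 0.92, 0.83, 0.64, 0.63 and -0.63 for the lists in the order given, then 0.45, 0.45 and -0.10.

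The spread of red blood cell transcripts is given as values, without a test between diets. The list mean was 0.32 ± 0.68 in 10 restricted and 0.05 ± 0.22 in 10 ad libitum middle-aged mice, 0.19 ± 0.30 in 9 and -0.04 ± 0.21 in 10 young adults, and 0.16 ± 0.31 in 8 and 0.08 ± 0.35 in 10 old mice (SD). In old mice the difference between diets was 0.08 with all mice, -0.02 without mouse 11 and 0.16 without mouse 54. Hba-a1 stood at 0.99 ± 0.91 in restricted and 0.48 ± 0.37 in ad libitum middle-aged mice. The amount of blood left in the tissue was not measured.

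On the first component restricted mice had means of 14.66 ± 29.65 in 8 old, -7.65 ± 24.87 in 10 middle-aged and -4.72 ± 21.96 in 9 young adult mice, against -10.75 ± 16.49, -2.16 ± 20.41 and 5.36 ± 14.44 in 10 mice fed ad libitum at the same ages (SD). Across all 16896 probes the mean level of a probe and its correlation with the component had rho = -0.08, which is across probes and not across independent samples. The description of mouse 27 repeats that of mouse 1, and the arrays of these mice correlated with r = 0.862 (A) and 0.942 (B) across probes, no higher than the median pair at 0.942 and 0.954.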
